A study of Mus musculus with 43 samples.

How the data were processed

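Poly(A) RNA of pooled embryonic mouse hearts was sequenced with single-end reads in 43 libraries, per the labels. Whole hearts were pooled at embryonic day 9.5 (E9.5) and ventricles at E15.5, 4 embryos to a pool, per the labels. The labels disagree on whether an E9.5 pool of the Dll4 experiments held 8 or 9 embryos. Here 8 was recorded for every Dll4 knockout pool and 9 for every Dll4 wild-type pool, and 8 for all Notch1 pools. If this holds, pool size went with genotype in both Dll4 comparisons. Libraries of the Dll4, Notch1 and Jag1 experiments were made with TruSeq and read on a GAIIx, and those of the Jag2, double-knockout and MFng experiments with NEBNext on a HiSeq2500, per the labels. Read processing used CASAVA 1.8, cutadapt 1.6.1, Bowtie2 2.0.6, RSEM 1.2.3 and edgeR on GRCm38, per the submitters' processing notes. The annotation, the strand setting, the filters and the order of these steps are not stated there.

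The deposited values are CPM values (counts scaled to 1e+06) of an effective library size that the authors scaled, read from the values themselves: low values in each column were whole multiples of 1 step, within 0.1 of a step. Column totals ran from 975303 to 1.03755e+06. The 2 deposited columns with the highest totals (knockout 3 of the Dll4 Nfatc1-Cre group, 1.0273e+06, and knockout 2 of the Notch1 group) were taken as a normalized signal that the authors scaled in the same way. The step gave a whole number behind each value, which was taken as its count, and the sums were taken as the depth of each library. The 4 tables hold 47 columns of values, all of them mapped to the 43 libraries, with the 4 wild types of the Dll4 Nfatc1-Cre experiment in both E9.5 tables. Those 4 libraries differed gene by gene between the tables, with a standard deviation of the log2 ratio of 0.13 to 0.14. The values of a library thus depend on its table, in a way the notes do not record. The recovered counts of these libraries differ between the tables as well, so they need not be the original read counts. Depths, the check of counting noise, edgeR and DESeq2 rest on such recovered counts. Between wild-type group means of 2 experiments in a table, the observed difference was 0.404 of the one expected from replicates for the Dll4 drivers, 0.411 for Notch1 against Dll4 and 0.417 for Jag1 against Jag2. It was 0.828 for Jag1 against the double knockout and 1.22 for Jag2 against the double knockout. At 0.404 to 0.417, wild-type means lay closer together than unadjusted, independent experiments with such replicates would give. This argues against unadjusted values for those pairs, over 7850 to 7946 genes. For the double knockout an adjustment was left open. The kind of adjustment is not recorded, and its bearing on p-values and resemblances was not tested. Fold changes between experiments were not computed from raw levels.

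Every comparison set a knockout or gain-of-function group against the wild-type siblings of its own experiment. Values were analysed as log2(CPM + 1), which understates fold changes of genes with low values, and genes with at least 1 CPM in as many libraries as the smaller group holds were tested. limma 3.58.1 (trend and robust options) in R 4.3.3 gave log2 fold changes with standard errors (SE) and p-values, adjusted by Benjamini-Hochberg (BH) over all genes tested. A gene was called at an adjusted p under 0.05. The Dll4 comparisons shared a fit of 4 groups, as did the Jag2 and double-knockout comparisons, and the other comparisons were fitted with their own groups. Differences between 2 knockouts were tested as a contrast of their changes against the wild types of each, the one against Jag1 in a fit of all groups of that table. Pools were treated as separate samples, so p-values rest on the spread between pools. limma draws the spread of each gene toward one shared between genes. In the Notch1 and Jag1 fits (3 and 4 residual degrees of freedom) the median prior degrees of freedom was infinite. There the p of a typical gene rests on the shared spread, not on its own. For Jag2 and the double knockout the median prior was 34 and 33.6 against 6 residual.

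Genes were grouped by 32 lists of Notch components, cardiac cell types and functions, neighbouring tissues, metabolism and stress, written before the data were examined. Lists with at least 5 tested members were tested with camera (limma), which compares a list with all other genes, at a preset correlation between genes of 0.01, and again with the correlation estimated. Adjusted p-values of lists are BH values over the lists of a comparison. fry (limma) tested whether a list's genes moved, on balance, one way, without reference to other genes. The named genes were set by a rule written before the data were examined. It takes the manipulated genes, the 8 largest changes up and the 8 down among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries (names that are only model identifiers left out), up to 4 called members of each list, 10 genes (E9.5) or 9 genes (E15.5) named in advance, and the 5 smallest adjusted p-values of each difference. Genes outside the rule are marked in the text as chosen after their values were seen.

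Positions, exon lengths and GC content came from GENCODE release M21 on GRCm38, to which 14108 of 14282 gene identifiers of the Dll4 table matched, 13962 of 14128 for Notch1, 14222 of 14424 for the Jag table and 13894 of 14073 for MFng. Reads of near-identical genes (Hba-a1 and Hba-a2, Hspa1a and Hspa1b, ribosomal protein genes and their pseudogene copies) may be split between copies, so their single values are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

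Alternatives for the counts of called genes that were set before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 CPM, median-of-ratios scaling, equal column totals, quantile normalization, limma without trend and robust options, library quality weights, the replicate number as a block, other groups in the fit, pooled wild types, an adjusted p of 0.1, a 1.5-fold minimum, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, and each library left out in turn. Most of these were set for named and manipulated genes and lists as well. The count models, thresholds and pooled wild types were extended to named and manipulated genes, the pooled wild types to lists and the count models to the differences only after the data were seen. Also added then were a correction of each library for transcript length and GC content (loess, span 0.3) and, for Notch1, the 4 Dll4 wild types of its table as further controls. The methods were tested on simulated counts with 200 genes changed by known folds. Of genes changed 1.5-fold, limma recovered 71.6% in the design of each Dll4 comparison, 64.2% for Notch1, 85.1% for Jag1, 86.6% for Jag2, 88.1% for the double knockout and 92.5% for MFng. Of those changed 2-fold it recovered 94.0% for Dll4 with Nfatc1-Cre, 91.0% with Tie2-Cre and 95.5% for Notch1. With no trend simulated, false calls made up 3.28% (Dll4 with Nfatc1-Cre) to 6.44% (Jag1) of all limma calls. For edgeR they made up 3.89% (Dll4 with Tie2-Cre) to 7.32% (double knockout). For DESeq2 they made up 0.552% (Jag1) to 11% (Dll4 with Tie2-Cre). Changed genes were drawn from those with a mean of at least 5 CPM, and no adjustment between experiments was simulated. Counts were also simulated with no changed gene but a length trend of 0.15 log2 per doubling, a chosen strength. There limma called 118 (Notch1) to 2192 (MFng) genes, with 1777 for Jag1 and 1394 for the double knockout. After the length and GC correction it called 0 to 5. Replicate libraries differed by more than counting noise in all 48 pairs, with a chi-square per degree of freedom of 1.80 to 34.0. No read files were analysed here, and groups of different stages were not compared.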

Results

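The series measured poly(A) RNA in 43 samples of mouse embryonic heart, in 14 groups, to follow how the Notch pathway acts while the ventricles form. The ligands Dll4, Jag1 and Jag2 and the receptor Notch1 were removed by Cre recombinase in chosen cells, and manic fringe (MFng), a glycosyltransferase that modifies Notch receptors, was gained. In E9.5 whole hearts, Dll4 was removed with Nfatc1-Cre, active in the endocardium (4 knockout and 4 wild-type pools), or with Tie2-Cre, active in cells that include endothelium and endocardium (3 and 3), and Notch1 with Nfatc1-Cre (3 and 2). Which cells recombined in these libraries was not tested. In E15.5 ventricles, cTnT-Cre, active in cardiomyocytes, removed Jag1 (3 and 3), Jag2 (3 and 2) or both ligands (3 and 2), and Tie2-Cre drove MFng gain of function (4 and 4). Libraries held 3.82 to 42.3 M recovered counts (median 16.1) for Dll4 with Nfatc1-Cre, 5.14 to 9.07 for Dll4 with Tie2-Cre and 5.63 to 15.3 for Notch1. At E15.5 they held 4.43 to 7.26 M counts for Jag1, 9.04 to 25.0 for Jag2, 7.61 to 18.4 for the double knockout and 11.5 to 22.1 for MFng. A single count was worth 0.0237 to 0.258 CPM in the Dll4 Nfatc1-Cre libraries and 0.138 to 0.228 CPM in the Jag1 libraries.

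The manipulated gene moved in the intended direction in every library. Dll4 (chromosome 2, 119325784 to 119335962, GRCm38) fell from 10.8 ± 0.947 CPM (SD, n = 4) to 2.86 ± 0.945 (n = 4) with Nfatc1-Cre, a log2 change of −1.64 ± 0.167 (SE; adjusted p = 3.11e-05). With Tie2-Cre it fell from 10.8 ± 1.71 (n = 3) to 2.58 ± 0.430 (n = 3), by −1.72 ± 0.193 (adjusted p = 1.23e-04). Notch1 (chromosome 2, 26457903 to 26516663) fell from 50.8 ± 8.71 (n = 2) to 18.4 ± 4.63 (n = 3), by −1.43 ± 0.133. In ventricles, Jag1 (chromosome 2, 137081456 to 137116644) fell from 23.1 ± 1.19 (n = 3) to 10.9 ± 1.43 (n = 3) in its own knockout, by −1.02 ± 0.108, and by −1.20 ± 0.0989 in the double knockout. Jag2 (chromosome 12, 112907819 to 112929776) fell from 28.8 ± 1.84 (n = 2) to 18.3 ± 0.881 (n = 3) in its own knockout, by −0.63 ± 0.0947 (adjusted p = 2.05e-04), and by −0.59 ± 0.0947 in the double knockout (adjusted p = 3.45e-04). In limma without trend and robust options neither passed (adjusted p = 0.137 and 0.110), nor did Jag1 in its own knockout (adjusted p = 0.101). Mfng (chromosome 15, 78755882 to 78773475) rose from 16.6 ± 3.09 (n = 4) to 104 ± 5.97 CPM (n = 4), by 2.59 ± 0.116. No excess of called genes within 10 Mb of a manipulated gene passed a test: 17.9% were called there against 15.1% elsewhere for MFng (one-sided Fisher's exact p = 0.153) and 5.26% against 3.86% for Jag1 (p = 0.279). Other comparisons had p-values from 0.606 to 1.

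**Figure D1:**
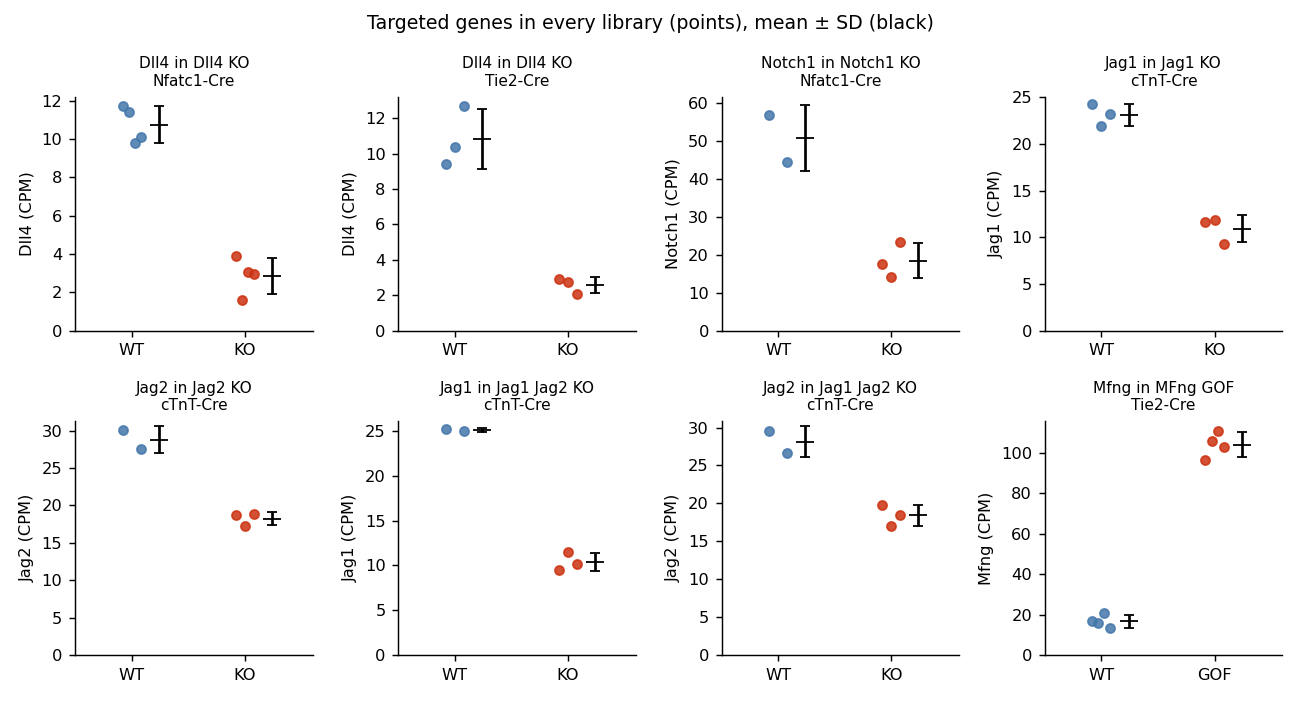
Normalized level (CPM) of each manipulated gene in every library, wild types in blue and knockouts or gain of function in red, with group mean and SD in black. The Dll4 knockouts lie at 1.59 to 3.87 CPM (Nfatc1-Cre) and 2.09 to 2.89 CPM (Tie2-Cre), below all their wild types at 9.43 to 12.7 CPM, and all MFng gain-of-function libraries lie at or above 96.4 CPM.

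Loss of Dll4 with Nfatc1-Cre asked what Dll4 does in the endocardium of the E9.5 heart. Some Notch targets fell: Heyl, a Notch-induced repressor, from 2.58 ± 0.543 to 1.21 ± 0.334 CPM (n = 4 each; log2 −0.70 ± 0.166, adjusted p = 0.0187), and Nrarp, a feedback inhibitor, by −0.41 ± 0.106 (adjusted p = 0.0274). Hey1 (0.00 ± 0.102), Hey2 (0.14 ± 0.112) and Efnb2 (−0.06 ± 0.0661) did not pass, and the list of Notch targets had 3 members down of 13 (3 down and 1 up adjusted over the list alone). It was not called (camera adjusted p = 0.370, and adjusted p = 0.560 with an estimated correlation). Of these 3 falls, 1 was that of Dll4 itself, the deleted gene, which is on the list. Trabecular genes moved both ways, with 3 up and 3 down of 17 (4 and 5 adjusted over the list alone). The natriuretic peptide gene Nppa rose from 765 ± 53.7 to 1509 ± 297 CPM (0.96 ± 0.176) and Ankrd1 by 0.64 ± 0.134. The trabecular regulator Cited1 fell by −0.49 ± 0.103 and the connexin gene Gja5 by −0.67 ± 0.146. Bmp10 (0.25 ± 0.0831, adjusted p = 0.0705), Irx3 (−0.57 ± 0.180, adjusted p = 0.0629), Nrg1 (−0.07 ± 0.161) and Erbb4 (0.31 ± 0.129) did not pass.

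In the same hearts some vessel genes rose: Apln by 2.17 ± 0.297, the endothelial transcription factor gene Sox17 by 1.01 ± 0.201, Flt1 by 0.51 ± 0.111 and Egfl7 by 0.42 ± 0.0879. As lists, endothelium was higher (3 up and 1 down of 23; 4 and 1 adjusted over the list alone; camera adjusted p = 0.0473; adjusted p = 0.530 with an estimated correlation) and arterial endothelium lower (1 up and 2 down of 12; 1 and 5 adjusted over the list alone; camera adjusted p = 0.0427; adjusted p = 0.435 with an estimated correlation). Both calls ended when some single libraries were left out (highest adjusted p 0.134 for the former, without knockout 3, and 0.0859 for the latter, without knockout 1). They also ended after correction for length and GC content (adjusted p = 0.0511 for each). The arterial list holds Dll4, the deleted gene, so 1 of its falls was set by the deletion. That list was not tested without Dll4. Genes of hypoxia and glycolysis rose as a group, 12 of 21 (16 adjusted over the list alone), including Vegfa from 100 ± 7.12 to 295 ± 89.5 CPM, Hk2 and Slc2a1 (camera adjusted p = 4.53e-13, and adjusted p = 0.435 with an estimated correlation). Amino acid stress genes, which the factor Atf4 controls, rose in 12 of 15 (13 adjusted over the list alone), among them Chac1 by 3.23 ± 0.341, Atf5 by 1.29 ± 0.184 and Atf4 by 0.78 ± 0.116 (camera adjusted p = 8.93e-16, and adjusted p = 0.435 with an estimated correlation). Chac1 (start 119351229) lies close to Dll4 on chromosome 2. Heat shock and immediate early genes rose in 6 of 14 (8 adjusted over the list alone), such as Hspa1a by 1.97 ± 0.337 (camera adjusted p = 1.22e-06, and adjusted p = 0.435 with an estimated correlation). Cell division genes fell in 3 of 22 (5 adjusted over the list alone), Rrm2 by −0.45 ± 0.123 (camera adjusted p = 4.69e-04, and adjusted p = 0.463 with an estimated correlation). The inhibitor genes Cdkn1a (0.95 ± 0.226) and Cdkn1b (0.55 ± 0.136) rose and Cdkn1c fell by −0.54 ± 0.120.

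Among genes with large rises were some of other tissues or of metabolism. Sncb, a synuclein gene of neurons, went from 0.275 ± 0.326 to 59.7 ± 27.0 CPM, the amino acid transporter gene Slc7a3 from 2.59 ± 0.518 to 51.4 ± 15.8 and Ndufa4l2, which overlaps Shmt2 in the annotation, from 3.51 ± 1.54 to 48.0 ± 22.9. The platelet gene Pf4 (2.15 ± 0.478) and the epicardial keratin gene Krt19 (2.08 ± 0.390) rose, while their lists had medians near 0 and were not called (leukocytes, camera adjusted p = 0.235; epicardium, 0.220). Erythroid genes were higher as a list (median 0.39; camera adjusted p = 1.38e-04; adjusted p = 0.530 with an estimated correlation), as were ribosomal proteins (median 0.14; camera adjusted p = 1.88e-04; adjusted p = 0.530 with an estimated correlation). Sex-linked genes, listed to show pool composition, were higher too (4 of 5 adjusted over the list alone; median 0.87; camera adjusted p = 0.0102; adjusted p = 0.435 with an estimated correlation). That list joins Xist, of females, with the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, so it mixes opposite signs. The share of male embryos may thus differ between knockout and wild-type pools, and its part in other calls was not tested. Conduction system genes were lower (2 of 13 down; 1 up and 4 down adjusted over the list alone; camera adjusted p = 0.0339, and 0.0539 without wild type 1; adjusted p = 0.443 with an estimated correlation). Mitochondrial transcripts fell in 2 of 13 (8 adjusted over the list alone; median −0.40; camera adjusted p = 3.65e-05; adjusted p = 0.530 with an estimated correlation). Besides Dll4, falls included Igfbpl1 (−1.28 ± 0.221) and Eef1a2 (−1.20 ± 0.258). Of 13537 genes tested, 677 rose and 449 fell (limma), 153 of them at least 2-fold, and edgeR called 1483 and DESeq2 1642. Leaving out knockout 2, 3 or 4 or any of wild types 1 to 4 moved the 1126 calls by over 1.5 times, to between 355 and 1752.

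Loss of Dll4 with Tie2-Cre asked the same of a wider set of cells that includes endothelium and endocardium. As a list, endothelial genes were higher: 12 of 23 up and 2 down (12 and 3 adjusted over the list alone; camera adjusted p = 0.00703; adjusted p = 0.579 with an estimated correlation). In pooled whole hearts a larger share of endothelial cells cannot be told from higher levels per cell. The VEGF receptor genes Kdr (from 148 ± 14.0 to 233 ± 12.3 CPM; 0.66 ± 0.0920) and Flt1 (0.85 ± 0.128) rose, as did Sox7 (0.76 ± 0.163) and Pecam1 (0.46 ± 0.101). The arterial genes Gja5 (−0.63 ± 0.168) and Bmx (−1.03 ± 0.206) fell, and the arterial factor gene Sox17 rose by 1.21 ± 0.232. Receptor genes Notch3 (0.78 ± 0.167) and Notch4 (0.56 ± 0.162) rose and the ligand gene Dll1 fell by −0.88 ± 0.238. In all, 7 Notch components rose and 2 fell of 18 (the same adjusted over the list alone). These falls were those of Dll1 and of Dll4, the deleted gene. Hey2 rose by 0.38 ± 0.129 (adjusted p = 0.0417). Hey1 (−0.04 ± 0.118), Heyl (0.03 ± 0.193), Nrarp (−0.31 ± 0.122, adjusted p = 0.0734), Efnb2 (0.09 ± 0.0762), Nrg1 (−0.23 ± 0.187), Bmp10 (−0.12 ± 0.0959), Nppa (−0.10 ± 0.202) and Irx3 (0.44 ± 0.208) did not pass.

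Muscle and trabecular genes of these hearts moved too. The neuregulin receptor gene Erbb4 rose by 0.62 ± 0.149 and Irx1 by 0.73 ± 0.198, while Smpx (−0.64 ± 0.148), Cited1 (−0.48 ± 0.119), Myh6 (−0.46 ± 0.109) and Tnnc1 (−0.45 ± 0.109) fell. Atrial genes had 6 members down and 1 up of 13 (7 and 1 adjusted over the list alone), with Kcna5 at −0.99 ± 0.136 (camera adjusted p = 0.0121, and 0.0628 without knockout 2; adjusted p = 0.579 with an estimated correlation). Sarcomere genes were lower as a list, 5 down and 1 up of 24 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0166, and 0.173 without wild type 2; adjusted p = 0.785 with an estimated correlation). All 13 transcripts of the mitochondrial genome fell (13 adjusted over the list alone), mt-Nd1 from 3481 ± 517 to 1401 ± 515 CPM (camera adjusted p = 2.85e-08, and adjusted p = 0.579 with an estimated correlation). Cell division genes fell in 11 of 22 (14 adjusted over the list alone), Rrm2 by −0.97 ± 0.142 and Pcna by −0.42 ± 0.0866 (camera adjusted p = 7.96e-06, and adjusted p = 0.579 with an estimated correlation). Hypoxia and glycolysis genes rose in 14 of 21 (18 adjusted over the list alone), Hk2 by 1.02 ± 0.209 (camera adjusted p = 2.85e-08, and adjusted p = 0.579 with an estimated correlation). Amino acid stress genes rose in 12 of 15 with 1 down (the same adjusted over the list alone), Psat1 by 0.74 ± 0.0994 (camera adjusted p = 8.50e-07, and adjusted p = 0.579 with an estimated correlation). Erythroid genes rose in 3 of 15 (1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.00204, and adjusted p = 0.746 with an estimated correlation). Heat shock and immediate early genes rose in 5 of 14 (7 up and 1 down adjusted over the list alone; camera adjusted p = 0.0144, and 0.151 without wild type 3; adjusted p = 0.785 with an estimated correlation). Ribosomal proteins rose in 8 of 30 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00703, and 0.161 without wild type 3; adjusted p = 0.798 with an estimated correlation). Neural crest and glia genes rose in 3 of 7 (3 adjusted over the list alone; camera adjusted p = 0.0240, and 0.0782 without knockout 2; adjusted p = 0.579 with an estimated correlation). The pharyngeal gene Tbx1 rose by 1.49 ± 0.362 and the neural crest gene Tfap2a by 1.65 ± 0.304. The outflow gene Hand2 fell by −0.65 ± 0.127. Tom1 rose from 14.5 ± 25.1 to 396 ± 195 CPM, with wild types that differed widely, and was not called with DESeq2 (adjusted p = 0.0885) or when knockout 3 or wild type 3 was left out. Besides Dll4, falls included those of Vcp-rs, the lymphatic and macrophage gene Lyve1 (−1.49 ± 0.191) and the matrix gene Postn (−1.37 ± 0.327). In all, 1580 genes rose and 1523 fell of 13671 (limma; edgeR 2580 and DESeq2 2460 calls). The 3103 calls became 1636, 1151 and 1719 without knockout 1, knockout 3 or wild type 3.

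Whether the driver matters was tested as the difference of the Dll4 changes. It differed for 30 of 14089 genes (limma; 11 higher and 19 lower with Nfatc1-Cre). The count was 1 with edgeR, 25 with DESeq2, 5 with a pseudocount of 0.1 and 15 to 47 with 1 library left out. Of 100 regroupings of the libraries, 5 reached it, the real one included. The others of these kept the knockouts wholly or mostly apart by driver, so they cannot decide on chance, which was not excluded. The genes included Sncb (difference 5.09 ± 0.429, adjusted p = 2.86e-05) and Nxph4 (3.14 ± 0.396). Gm26582 and Gm9923 were at 9.52 ± 0.454 and 23.4 ± 16.7 CPM in the Tie2-Cre knockouts and listed at 0 in their wild types. Gm4673, which overlaps Lsr in the annotation, was at 17.8 ± 12.8 CPM in the Nfatc1-Cre knockouts and listed at 0 in theirs. Chosen after its values were seen, Lyve1 fell with Tie2-Cre alone (difference 1.35 ± 0.253, adjusted p = 0.0409). For Heyl (−0.73 ± 0.255, adjusted p = 0.297), Nppa (1.06 ± 0.268, adjusted p = 0.185), Kdr (−0.50 ± 0.122, adjusted p = 0.146) and Notch3 (−0.57 ± 0.222, adjusted p = 0.363) the difference between drivers did not pass. Across 13376 genes tested in both, the changes correlated with a Pearson r of 0.639 (Spearman 0.623), genes not being independent replicates. Both drivers raised 391 genes against 71.4 expected from independent lists, both lowered 242 against 51.1, and not 1 called gene went opposite ways.

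Loss of Notch1 with Nfatc1-Cre asked what the receptor does in the same cells. Its targets Nrarp (from 10.2 ± 0.501 to 5.84 ± 0.615 CPM; −0.72 ± 0.193, adjusted p = 0.00755), Hes1 (−0.61 ± 0.164) and Dll4 (−0.80 ± 0.189) fell, and Myc rose by 0.49 ± 0.136. Of 13 Notch targets, 3 fell and 1 rose (the same adjusted over the list alone). Hey1 (−0.21 ± 0.121), Hey2 (0.14 ± 0.109), Heyl (−0.35 ± 0.257), Efnb2 (−0.21 ± 0.108), Nrg1 (0.46 ± 0.224) and Bmp10 (0.26 ± 0.126) did not pass. Trabecular genes had 4 members up and 1 down of 17 (4 and 2 adjusted over the list alone). Nppb rose by 0.75 ± 0.106, Nppa from 594 ± 132 to 839 ± 111 CPM (0.51 ± 0.104), Ankrd1 by 0.44 ± 0.104 and Erbb4 by 0.35 ± 0.107, and Irx3 fell by −0.56 ± 0.168. Kdr (0.54 ± 0.105), Sox7 (0.65 ± 0.140) and Egfl7 (0.57 ± 0.109) rose, 3 of 23 endothelial genes (8 up and 1 down adjusted over the list alone; camera adjusted p = 4.86e-04; adjusted p = 0.447 with an estimated correlation). The vessel genes Cxcr4 (−0.90 ± 0.235), Car4 (−0.89 ± 0.151) and Lyve1 (−1.21 ± 0.226) fell, and the matrix gene Fbln2 rose by 0.87 ± 0.112.

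The Notch1 libraries also differed in markers of blood, epicardium and endoderm. Erythroid genes rose in 13 of 15 (13 adjusted over the list alone), the embryonic globin gene Hbb-y from 3846 ± 949 to 9146 ± 708 CPM (camera adjusted p = 1.34e-42, and adjusted p = 0.0872 with an estimated correlation). Epicardial genes rose in 9 of 12 (9 adjusted over the list alone), Upk3b by 0.96 ± 0.114 and Tbx18 by 0.67 ± 0.110 (camera adjusted p = 8.63e-15, and adjusted p = 0.0603 with an estimated correlation). Endoderm and liver genes fell in 9 of 11 (10 adjusted over the list alone), Apob from 8.27 ± 2.18 to 0.261 ± 0.173 CPM and Apoa1 by −2.45 ± 0.265 (camera adjusted p = 4.31e-37, and adjusted p = 0.0603 with an estimated correlation). In pooled whole hearts a different share of blood, epicardium or neighbouring tissue cannot be told from changed levels per cell. Hypoxia and glycolysis genes rose in 10 of 21 (15 adjusted over the list alone), Egln3 by 1.44 ± 0.153, Ndrg1 by 1.56 ± 0.173 and Bnip3 by 0.92 ± 0.104 (camera adjusted p = 1.60e-16, and adjusted p = 0.0872 with an estimated correlation). The second heart field genes Tbx1 (−1.19 ± 0.288) and Isl1 (−0.68 ± 0.184) fell, and their list was lower (camera adjusted p = 0.0310, and 0.298 without wild type 2; adjusted p = 0.447 with an estimated correlation). Leukocyte genes rose in 2 of 6 (5 adjusted over the list alone; camera adjusted p = 0.00793; adjusted p = 0.403 with an estimated correlation). Lists that were higher, but not when some single libraries were left out, were fibroblasts (camera adjusted p = 0.00210), heat shock and immediate early genes (0.00456), amino acid stress (0.0269; adjusted p = 0.447 with an estimated correlation for each) and fatty acid oxidation (camera adjusted p = 0.0346, and adjusted p = 0.552 with an estimated correlation). The protease gene Ctss, of macrophages, went from 0.162 ± 0.230 to 10.2 ± 4.13 CPM, and Aqp5 rose by 2.31 ± 0.246. Of 13639 genes, 426 rose and 155 fell (limma; edgeR 586 and DESeq2 269 calls). The 581 calls became 374 without knockout 3 and 242 without wild type 2. They became 153 without trend and robust options, 1398 with library weights, 1084 with the Dll4 wild types added and 1047 after length and GC correction. Genes raised in the Notch1 and the Dll4 Nfatc1-Cre knockouts numbered 115 against 18.8 expected, those lowered in both 5 against 4.95, and 8 went opposite ways (r = 0.302 across 13325 genes). Against the Dll4 Tie2-Cre knockouts, 151 rose in both against 45.2 expected, 13 fell in both against 17.1 and 27 went opposite ways (r = 0.204).

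**Figure D2:**
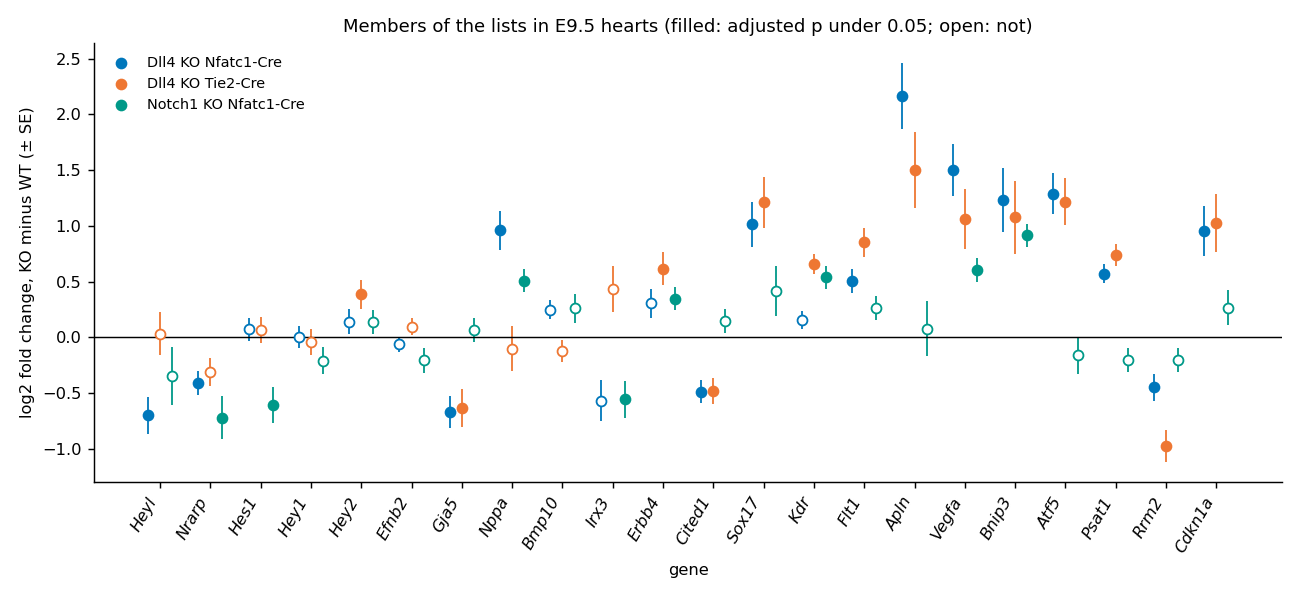
Log2 fold change (± SE) of 22 list members in the E9.5 knockouts of Dll4 with Nfatc1-Cre (blue), Dll4 with Tie2-Cre (orange) and Notch1 (green), filled where the adjusted p (limma) was under 0.05. Nrarp lies at −0.41, −0.31 and −0.72 and Bnip3 at 1.23, 1.08 and 0.92.

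Loss of Jag1 from cardiomyocytes asked what this ligand of the myocardium does in the E15.5 ventricle. Changes were small: of 545 called genes, 465 moved less than 1.5-fold. Matrix genes of the cardiac jelly had 4 members up and 1 down of 12 (5 and 1 adjusted over the list alone; camera adjusted p = 3.88e-05; adjusted p = 0.251 with an estimated correlation). Hapln1 rose by 0.78 ± 0.174, Fbln2 from 101 ± 2.92 to 141 ± 9.62 CPM (0.47 ± 0.0514) and Vcan by 0.22 ± 0.0398, and Fbln1 fell by −0.19 ± 0.0551. Collagen genes Col1a1 (0.24 ± 0.0349) and Col1a2 (0.24 ± 0.0365), the inhibitor gene Cdkn1a (0.45 ± 0.0771), the calcium exchanger gene Slc8a1 (0.30 ± 0.0368) and Notch1 itself (0.19 ± 0.0523) rose. The trabecular and conduction connexin gene Gja5 fell by −0.21 ± 0.0493 (adjusted p = 0.00161) and the taurine transporter gene Slc6a6 rose by 0.23 ± 0.0460. The Notch targets Hey1 (0.10 ± 0.103), Hey2 (−0.12 ± 0.0475, adjusted p = 0.144) and Heyl (−0.24 ± 0.0883, adjusted p = 0.108) did not pass, and neither did Tbx20 (−0.06), Mycn (−0.04), Bmp10 (0.07), Nppa (0.12) or Fabp4 (0.05).

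Ribosomal protein genes fell in 6 of 30 in the Jag1 knockouts (10 adjusted over the list alone), by small amounts such as −0.17 ± 0.0391 for Rplp1 (camera adjusted p = 4.02e-09, and adjusted p = 0.375 with an estimated correlation). Hypoxia and glycolysis genes rose in 4 of 21 (9 adjusted over the list alone), Aldoa by 0.13 ± 0.0333 (camera adjusted p = 6.65e-06, and adjusted p = 0.488 with an estimated correlation). Epicardial genes Lrrn4 (0.55 ± 0.117) and Upk1b (0.52 ± 0.149) rose, 4 of 14 (5 adjusted over the list alone; camera adjusted p = 0.0151, and 0.227 without wild type 1; adjusted p = 0.488 with an estimated correlation), and the embryonic globin gene Hba-x fell by −0.55 ± 0.128. Mitochondrial transcripts rose in 2 of 13 (2 adjusted over the list alone; camera adjusted p = 0.00328, and 0.154 without wild type 1; adjusted p = 0.649 with an estimated correlation). Cell division genes fell in 1 of 22 (5 adjusted over the list alone; camera adjusted p = 0.00237, and 0.0650 without wild type 2; adjusted p = 0.488 with an estimated correlation). Erythroid genes were lower as a list (median −0.25; camera adjusted p = 2.95e-05; adjusted p = 0.488 with an estimated correlation). The macrophage gene Csf1r rose by 0.43 ± 0.0832, while the leukocyte list was not called (median −0.02; camera adjusted p = 0.819). Lenep, which overlaps Flad1 in the annotation, stood at 9.11 ± 6.19 CPM in the knockouts and was listed at 0 in all 3 wild types. Other large changes were rises of Pappa (0.93 ± 0.169), Angptl7 (0.85 ± 0.179) and Lrp2 (0.80 ± 0.145) and falls of Rps13 (−0.70 ± 0.0904) and Ndufs5 (−0.59 ± 0.0669). Of 13769 genes, 362 rose and 183 fell (limma; edgeR 447 and DESeq2 84 calls). Without trend and robust options limma made 2 calls, and without knockout 2 or wild type 2 the 545 became 335 and 354.

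Loss of Jag2 from cardiomyocytes changed 5 of 13927 genes (limma; edgeR 4 and DESeq2 8 calls, and 500 genes at an unadjusted p under 0.05). Besides Jag2, they included Socs2, an inhibitor of cytokine signals, which rose from 21.4 ± 0.146 (n = 2) to 42.0 ± 2.74 CPM (n = 3; 0.94 ± 0.0841, adjusted p = 4.96e-10). Another was Lingo2 (chromosome 4, 35706647 to 36951747), at 6.76 to 9.97 CPM and listed at 0 in wild types. Named because few genes were called, after their values were seen, the others were Pou3f2, a neural transcription factor gene (1.51, adjusted p = 7.51e-05), and B230217C12Rik, a transcript listed at 0 in wild types. Hey1 (−0.05 ± 0.105), Hey2 (−0.07 ± 0.0579), Heyl (−0.01 ± 0.0875), Tbx20 (−0.03), Mycn (0.09), Bmp10 (−0.01), Nppa (0.08), Gja5 (0.10) and Fabp4 (−0.11) all had an adjusted p of 0.999. Hypoxia and glycolysis genes were lower as a list, with 3 members down adjusted over the list alone (camera adjusted p = 2.90e-06, and adjusted p = 0.379 with an estimated correlation). Leukocyte genes were higher (camera adjusted p = 2.90e-04, and 0.541 without knockout 2), as were ribosomal proteins (0.0341, and 0.541 with a median under 0 without knockout 2), and fatty acid oxidation was lower (camera adjusted p = 1.76e-05, and 0.0959 without wild type 1; adjusted p = 0.899 with an estimated correlation for each). The count became 9 without knockout 1, knockout 3 or wild type 2. It became 12 with library weights, 22 with only the 2 groups in the fit, and 2 without trend and robust options. With the replicate number as a block, where pairing was not excluded, it became 58.

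Loss of both Jag ligands asked whether Jag1 and Jag2 stand in for each other in the ventricle. Endothelial genes rose in 3 of 23 (11 adjusted over the list alone), Plvap from 53.3 ± 0.559 (n = 2) to 74.3 ± 3.21 CPM (n = 3; 0.47 ± 0.0708, adjusted p = 8.77e-05), Tie1 by 0.26 ± 0.0564 and Eng by 0.26 ± 0.0584 (camera adjusted p = 6.61e-10, and adjusted p = 0.123 with an estimated correlation). Lists of other cells moved both ways. Capillary and venous genes rose in 2 of 11 (4 adjusted over the list alone; camera adjusted p = 6.50e-04; adjusted p = 0.123 with an estimated correlation). Conduction system genes rose in 1 of 13 (3 adjusted over the list alone; camera adjusted p = 0.00616; adjusted p = 0.123 with an estimated correlation). Sarcomere genes (camera adjusted p = 0.00368, and 0.0897 without wild type 2; adjusted p = 0.367 with an estimated correlation) and atrial genes (camera adjusted p = 0.00616, and 0.130 without wild type 1; adjusted p = 0.178 with an estimated correlation) were higher. Lower were erythroid genes (median −0.26; camera adjusted p = 0.00173, and 0.412 without wild type 2; adjusted p = 0.490 with an estimated correlation) and leukocyte genes (median −0.23; camera adjusted p = 0.0235, and 0.210 without wild type 1; adjusted p = 0.537 with an estimated correlation). Hypoxia and glycolysis genes rose in 4 of 21 (10 adjusted over the list alone), Eno1 by 0.35 ± 0.0508 (camera adjusted p = 6.61e-10, and adjusted p = 0.123 with an estimated correlation). Trabecular genes rose in 2 of 17 (3 adjusted over the list alone), Slc6a6 by 0.29 ± 0.0561 and the transcription factor gene Irx3 by 0.41 ± 0.0948 (camera adjusted p = 5.34e-04, and adjusted p = 0.178 with an estimated correlation). Nkx2-5, a cardiac transcription factor gene, rose by 0.24 ± 0.0616, Cdkn1a by 0.59 ± 0.0851 and Fbln2 by 0.41 ± 0.0601, and Ppargc1a, a regulator of mitochondria, fell by −0.31 ± 0.0620. Hey2 (−0.20 ± 0.0578, adjusted p = 0.0848), Tbx20 (−0.16 ± 0.0518, adjusted p = 0.130), Hey1 (0.06), Heyl (−0.02), Mycn (−0.01), Bmp10 (0.13), Nppa (0.32), Gja5 (0.01) and Fabp4 (0.24) did not pass. Ribosomal protein genes rose in 3 of 30 (19 up and 1 down adjusted over the list alone), Rpl11 by 0.30 ± 0.0575 (camera adjusted p = 1.60e-14, and adjusted p = 0.241 with an estimated correlation). Amino acid stress genes were higher (camera adjusted p = 0.0169, and 0.147 after length and GC correction; adjusted p = 0.241 with an estimated correlation). Large changes were those of Lingo2 (8.97 ± 2.48 CPM against 0.0610) and Pou3f2 (chromosome 4, 22482780 to 22488366; 8.87 ± 1.84 against 0.0601), and Angptl7 rose by 0.99 ± 0.178. Besides the ligands, Epha3 (−0.53 ± 0.124) and Bmp5 (−0.50 ± 0.111) fell. Of 13842 genes, 105 rose and 31 fell (limma; edgeR 156 and DESeq2 113 calls). The 136 calls became 79 without knockout 2, 488 without knockout 3, 45 without wild type 1 and 24 without wild type 2, 5 without trend and robust options, 261 with library weights and 331 with only the 2 groups in the fit.

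**Figure D3:**
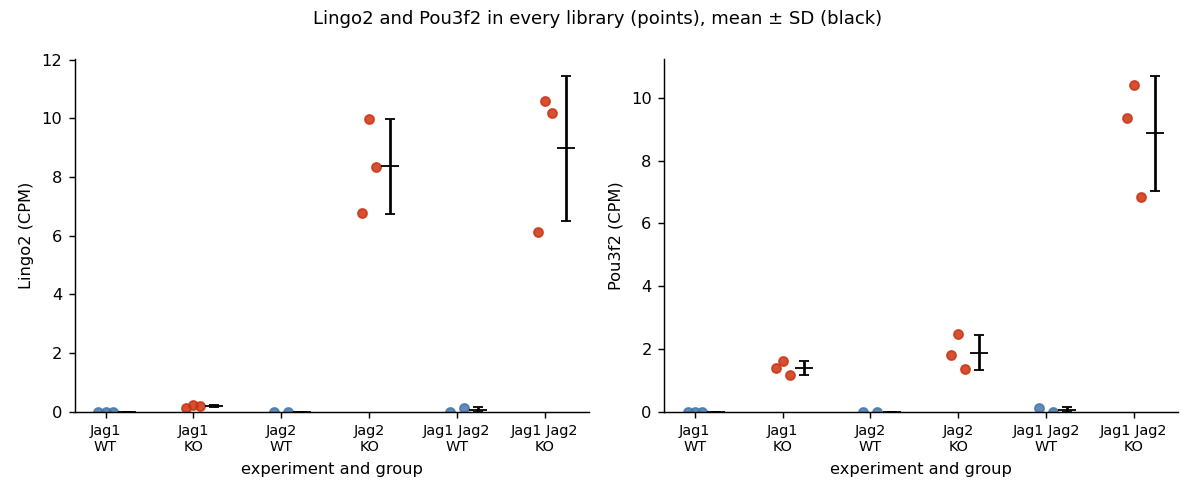
Level (CPM) of Lingo2 and Pou3f2 in every library of the Jag1, Jag2 and double-knockout experiments, wild types in blue and knockouts in red, with mean and SD in black. Lingo2 lies at 6.76 to 9.97 CPM in the Jag2 knockouts and at most 0.228 CPM in the Jag1 knockouts, and Pou3f2 is highest in the double knockouts (6.83 to 10.4 CPM).

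Tested directly, the double knockout differed from the Jag2 knockout in 6 of 14163 genes (limma). This count was unstable, at 53 without Jag2 knockout 2. Jag1 (−1.24 ± 0.140), Cdkn1a (0.68 ± 0.121, adjusted p = 0.00484), Eno1 (0.40 ± 0.0717) and Pou3f2 (1.70 ± 0.301; edgeR −0.81, its adjusted p = 0.885) were among the 6. Gm9913, which overlaps Fbn1 in the annotation, was at 16.8 ± 6.21 CPM in the double knockouts and listed at 0 in their wild types. From the Jag1 knockout the double knockout differed in 24 of 14190 genes, with Gm9913 and Lenep, and Lingo2 (2.96 ± 0.290), Pou3f2 (1.96 ± 0.288; edgeR −0.10) and Rpl11 (0.45 ± 0.0692, adjusted p = 0.00139). The 24 became 7 without double knockout 2 and 162 without double knockout 3. Chosen after its values were seen, Slc8a1 was lower by −0.33 ± 0.0666 in that difference (adjusted p = 0.0320). Hey2 did not pass in either difference (−0.13 ± 0.0818 and −0.08 ± 0.0702). Changes of the Jag1 and the double knockouts correlated weakly (r = 0.0764 across 13624 genes), with 25 genes raised in both against 2.59 expected, 3 lowered in both against 0.405 and 2 opposite. Those of the Jag2 and the double knockouts had r = 0.0904. For the Jag1 and Jag2 knockouts, r was 0.0562 and the Spearman correlation −0.0498.

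Gain of MFng with Tie2-Cre asked what happens when Notch receptors are shifted toward Delta ligands at the time the ventricular wall compacts. Some peptide and trabecular genes rose: Nppb from 101 ± 4.05 to 215 ± 14.0 CPM (n = 4 each; 1.08 ± 0.0453, adjusted p = 5.11e-11), Ankrd1 by 0.64 ± 0.0365, Nppa by 0.67 ± 0.129, Bmp10 by 0.53 ± 0.0802 and Slc6a6 by 0.41 ± 0.0454. Erbb2 (−0.33 ± 0.0481) and Gja5 (−0.27 ± 0.0528) fell, and of 17 trabecular genes 7 rose and 3 fell (7 and 4 adjusted over the list alone). The list was not called (camera adjusted p = 0.107, and adjusted p = 0.388 with an estimated correlation). Notch targets split, with 4 up and 3 down of 13 (5 and 3 adjusted over the list alone): Hey1 rose by 0.24 ± 0.0735, and Hey2 (−0.28 ± 0.0406), Heyl (−0.49 ± 0.0871) and Notch3 (−0.39 ± 0.0575) fell. Compact wall genes moved both ways, with the cyclin genes Ccnd1 (0.36 ± 0.0672) and Ccnd2 (0.24 ± 0.0379) and Fgfr1 (0.30 ± 0.0489) higher and Tbx20 lower by −0.15 ± 0.0403. Mycn (−0.01 ± 0.0570) and Fabp4 (0.03 ± 0.105) did not pass. Sarcomere genes fell in 10 of 24 and rose in 2 (11 and 3 adjusted over the list alone), Pln by −0.30 ± 0.0365 and Ldb3 by −0.16 ± 0.0293, and Myh6 rose by 0.28 ± 0.0636 (camera adjusted p = 0.00621, and 0.199 after quantile normalization; adjusted p = 0.388 with an estimated correlation). Ion channel genes fell in 6 of 15 (7 down and 1 up adjusted over the list alone), Kcnd2 by −0.53 ± 0.0898 (camera adjusted p = 4.80e-04, and adjusted p = 0.216 with an estimated correlation).

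Endothelial genes rose in 9 of 23 and fell in 2 with MFng (10 and 3 adjusted over the list alone). Eng rose by 0.47 ± 0.0437, Emcn by 0.54 ± 0.0546, Flt1 by 0.45 ± 0.0488 and Vwf by 0.86 ± 0.0902 (camera adjusted p = 0.0104, and adjusted p = 0.255 with an estimated correlation). Lyve1 rose from 6.34 ± 0.693 to 13.6 ± 1.33 CPM and the apelin receptor gene Aplnr fell by −1.10 ± 0.171. Pericyte and smooth muscle genes fell in 6 of 11 and rose in 2 (7 and 2 adjusted over the list alone), Mylk by −0.47 ± 0.0761 and Pdgfrb by −0.33 ± 0.0545 (camera adjusted p = 0.00532, and adjusted p = 0.255 with an estimated correlation). Heat shock and immediate early genes rose in 5 of 14 and fell in 1 (7 and 1 adjusted over the list alone), which camera called higher (adjusted p = 0.00582, and adjusted p = 0.218 with an estimated correlation). Matrix genes of the cardiac jelly rose in 8 of 12 (9 adjusted over the list alone), Has2 by 0.68 ± 0.157 and Fbln2 by 0.43 ± 0.0589 (camera adjusted p = 1.81e-04, and adjusted p = 0.0805 with an estimated correlation).

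Interferon response genes rose in 10 of 11 with MFng (10 adjusted over the list alone), Isg15 from 0.716 ± 0.303 to 7.90 ± 2.26 CPM, Irf7 by 1.81 ± 0.148 and Bst2 by 1.42 ± 0.111 (camera adjusted p = 2.35e-16, and adjusted p = 0.0805 with an estimated correlation). Macrophage genes rose in 6 of 13 (8 adjusted over the list alone), Mrc1 by 0.82 ± 0.0646 and C1qb by 0.79 ± 0.113 (camera adjusted p = 2.79e-06, and adjusted p = 0.255 with an estimated correlation). The chemokine gene Ccl2 rose by 2.75 ± 0.188. Hypoxia and glycolysis genes rose in 18 of 21 (18 adjusted over the list alone), Gapdh by 0.57 ± 0.0539 (camera adjusted p = 9.38e-19, and adjusted p = 0.218 with an estimated correlation). Amino acid stress genes rose in 11 of 15 (11 adjusted over the list alone), Asns by 1.71 ± 0.230 and Mthfd2 by 1.38 ± 0.177 (camera adjusted p = 1.34e-10, and adjusted p = 0.218 with an estimated correlation). Mitochondrial transcripts fell in 10 of 13 (12 adjusted over the list alone), mt-Nd4l by −0.43 ± 0.0731 (camera adjusted p = 2.08e-08, and adjusted p = 0.315 with an estimated correlation). Erythroid genes parted: the adult globin genes Hbb-bs (from 2607 ± 315 to 1041 ± 298 CPM; −1.36 ± 0.209), Hba-a1 (−1.14 ± 0.167) and Hba-a2 (−1.16 ± 0.269) fell with Alas2 (−1.37 ± 0.321). Hemgn (3.02 ± 0.253), Rhag (2.56 ± 0.314), Klf1 (1.83 ± 0.164) and Gata1 (1.13 ± 0.211) rose, and of 15 erythroid genes 6 rose and 5 fell (7 and 6 adjusted over the list alone). Of 13857 genes, 1219 rose and 860 fell (limma; edgeR 2052 and DESeq2 1947 calls), 1756 of them less than 1.5-fold. With the double Jag knockout, MFng gain shared 48 rises against 8.75 expected and 14 falls against 1.95, with 4 genes opposite (r = 0.148 across 13574 genes). With the Jag1 knockout it shared 102 rises against 30 and 23 falls against 11.6, with 26 opposite (r = 0.0746).

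**Figure D4:**
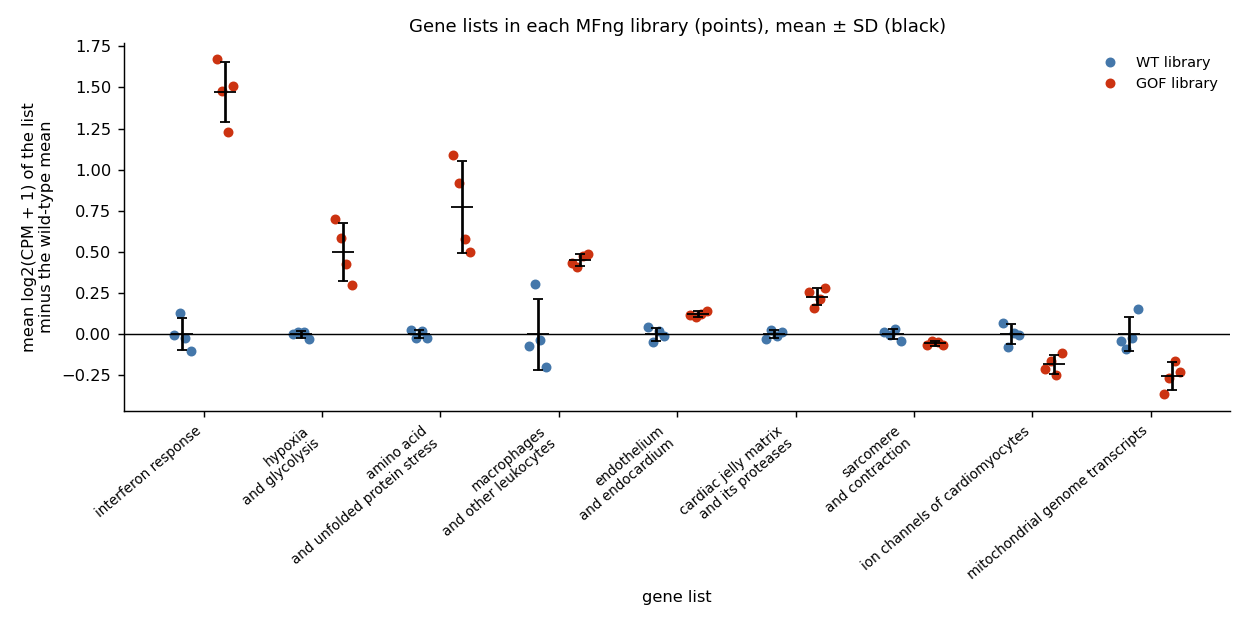
Mean log2(CPM + 1) of 9 gene lists in each MFng library minus the wild-type mean, wild types in blue and gain of function in red, with mean and SD in black. Gain-of-function libraries lie at 1.23 or above for the interferon response list, where the highest wild type lies at 0.13.

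Over all comparisons, camera called 69 of 206 list tests, 48 up and 21 down, at the preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.0603; at the preset correlation, 69). Of these 69, 34 were also called by fry, which called 35 and tests whether a list's genes move on balance one way, not against other genes. Genes of hypoxia and glycolysis were called up in every comparison except the Jag2 knockouts, where they were called down. In 30 of the 206 tests the median, the mean and the test of a list differed in sign, none of them a camera call. For the Notch targets this was so for Dll4 with Tie2-Cre (median 0.03, mean −0.03) and for Jag1 (median 0.01, mean 0.02, camera direction down). That list includes Dll4, whose deletion lowered its mean with Tie2-Cre.

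**Figure D5:**
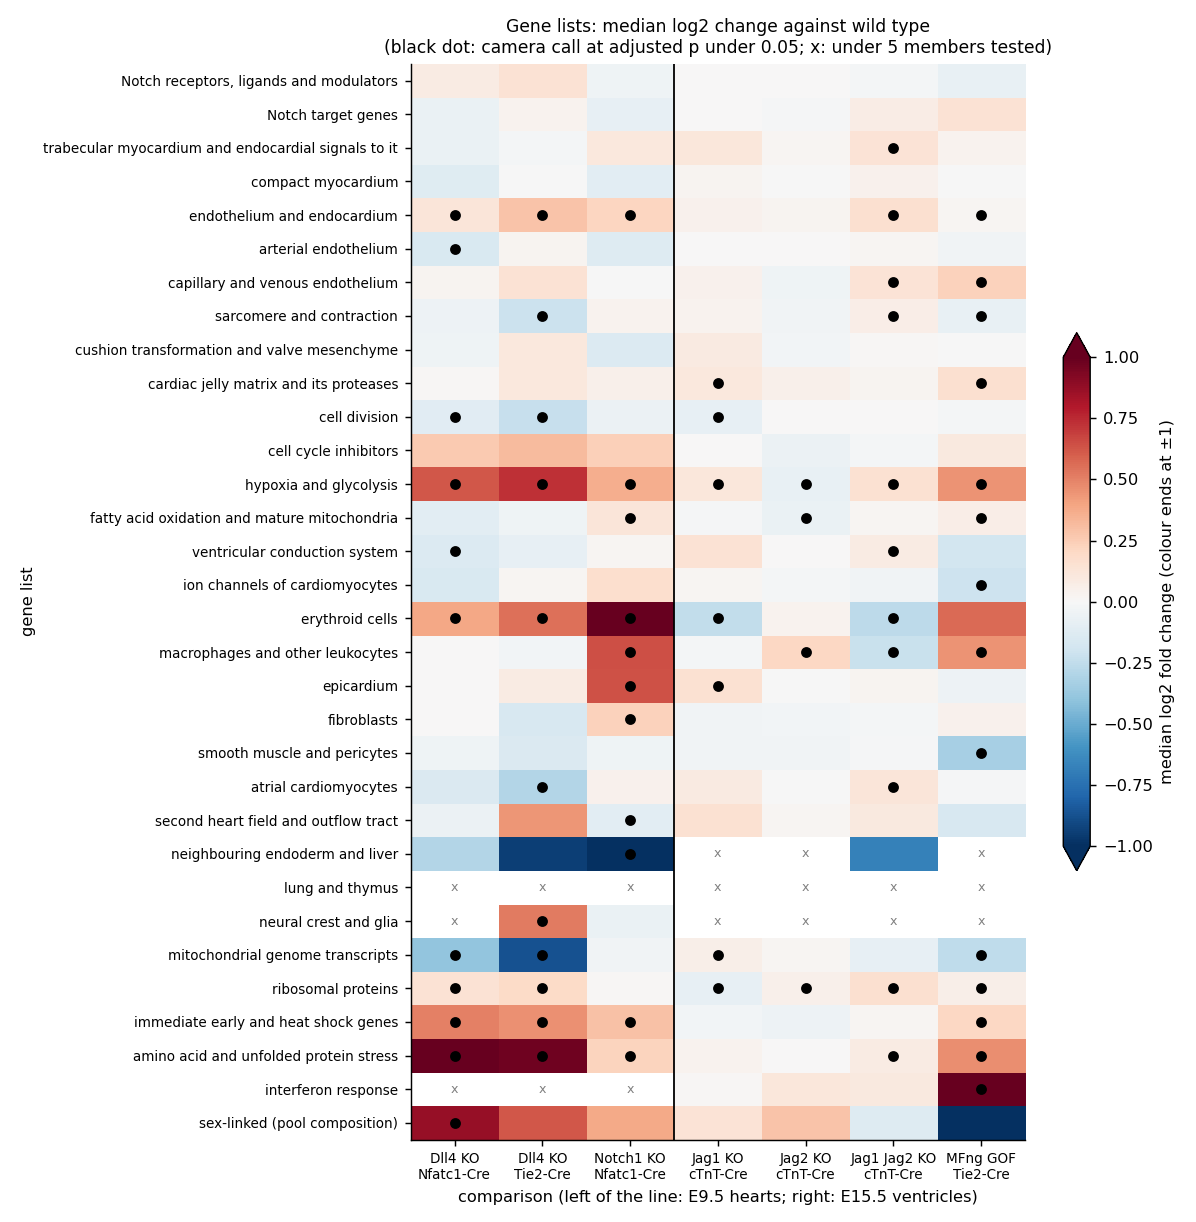
Median log2 fold change of the members of 32 gene lists (vertical) in the 7 comparisons (horizontal), coloured from −1 (blue) to 1 (red), with a black dot where camera called the list at its preset correlation and a cross where fewer than 5 members were tested. Hypoxia and glycolysis is dotted in all columns, with a median of 0.62 in the Dll4 Nfatc1-Cre knockouts.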

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

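Of the tests in this part, those on transcript length and GC content for the MFng interferon list, on library scores, on leukocyte genes and on splits of the libraries were chosen only after the data were seen. A result is singled out in this way by chance about 1 time in 20, and 19 of 492 groups of 4 libraries (3.86%) held a library set far apart from the others.

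A library lay far from the others of its group, against their spread, for 12 named genes, in CPM with the range of the other libraries. For Dll4 with Nfatc1-Cre these were Nxph4 in wild type 1 (0.208, others 0), Cited1 in wild type 1 (123.6, others 102.5 to 105.7) and Krt8 in knockout 4 (375.6, others 160.1 to 189.1). In the MFng wild types they were Alb in library 4 (27.52, others 4.253 to 6.035), Cxcr4 in library 3 (17.72, others 14.33 to 14.72), Gadd45a in library 4 (3.362, others 2.282 to 2.436), Fos in library 2 (3.518, others 2.429 to 2.566) and Irf7 in library 1 (1.693, others 1.239 to 1.316). In MFng gain of function they were Eno2 in library 4 (9.751, others 4.835 to 5.355), Fbln2 in library 1 (128.3, others 112 to 113.8), Ddr2 in library 4 (22.29, others 26.98 to 27.78) and Mycn in library 3 (36.32, others 40.21 to 41.01).

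Scores of 7 gene lists (mean log2 level minus the wild-type mean) had such a library too. For Dll4 with Nfatc1-Cre they were capillary and venous endothelium in knockout 1 (0.0996, others 0.348 to 0.354), and in wild type 4 ion channels (−0.0336, others 0.00931 to 0.0147), leukocytes (0.226, others −0.102 to −0.0495) and sex-linked genes (−0.56, others 0.116 to 0.242). Sex-linked genes follow the mix of male and female embryos in a pool, and a score over Xist and Y-linked genes mixes opposite signs. In MFng they were cushion mesenchyme in wild type 4 (0.0421, others −0.0167 to −0.01), smooth muscle in wild type 2 (0.0436, others −0.0205 to −0.0112) and epicardium in gain-of-function library 4 (−0.0332, others 0.0985 to 0.12).

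Changes that differed between knockouts were singled out because the difference itself passed its test. Between the drivers of the Dll4 knockouts 30 genes differed: Gm26582 by −3.37, Sncb by 5.09, Gm9923 by −4.46, Gm4673 by 3.84 and Nxph4 by 3.14 had the lowest adjusted p-values. Of 100 regroupings of the Dll4 libraries, 5 gave as many genes, the real one included, and the others of these gave 72, 94, 104 and 138. These 4 exceed the real count. Those with 72, 94 and 104 kept all 4 Nfatc1-Cre knockouts together. The one with 138 kept all Tie2-Cre knockouts together, with 1 Nfatc1-Cre knockout. They thus carry much of the difference between drivers themselves and cannot decide on chance. A chance origin of the 30 is not excluded. The double knockout differed from the Jag2 knockout in 6 genes, with Gm9913 at 4.10, Jag1 at −1.24, Cdkn1a at 0.68, Pou3f2 at 1.70 and Eno1 at 0.40. From the Jag1 knockout it differed in 24, with Gm9913 at 3.20, Lingo2 at 2.96, Lenep at −3.80, Pou3f2 at 1.96 and Rpl11 at 0.45.

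Splits of the libraries were compared with the real groups. Where the real groups differ, mixed splits carry that difference in their spread, which holds their calls down. The splits cannot tell genotype from anything else that differed between the groups, such as the recorded pool sizes for Dll4. For Dll4 with Nfatc1-Cre only 1 of 35 splits, the real one, gave 1126 calls, and the highest other gave 1. For MFng, 1 of 35 splits gave 2079 calls, and the highest other gave 2. For Dll4 with Tie2-Cre 1 of 10 splits gave 3103 calls (highest other 3), and for Jag1 1 of 10 gave 545 (highest other 8), where 10 splits are too few for a share under 0.05.

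Interferon genes rose with MFng gain of function (median log2 change 1.42). A few deviating libraries were not the source, since the lowest gain-of-function score was 1.23 and the highest wild-type score 0.13. Correction for transcript length and GC content left the list called (camera adjusted p = 1.10e-15; adjusted p = 0.0958 with an estimated correlation). Leukocyte genes rose less (median 0.452), so more leukocytes of unchanged composition would not alone give the size of the rise. A larger share of an interferon-rich cell type, which could be a kind of leukocyte, could not be excluded.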

How the results depend on the processing

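The cause was not tested for results that changed. Of 502 gene results, 465 were the same with edgeR, 497 with median-of-ratios scaling, 477 with quantile normalization, 491 with library weights, 339 without trend and robust options, 466 after length and GC correction and 294 with a 1.5-fold minimum, where 208 were weaker. With DESeq2, which gave no value for some, 394 were the same, 51 weaker and 2 stronger. With all 6 groups in the fit (Jag1), 28 were the same and 35 weaker. Of 206 list results, 202 were the same with quantile normalization and 192 after length and GC correction. The 8 resemblances, run only with the pseudocounts, filters and scalings, kept their direction, while small ones moved, such as Jag1 with Jag2 from 0.0562 to 0.105 and Jag2 with the double knockout from 0.0904 to 0.159 with a pseudocount of 0.1. Treated libraries were closest to the wild type of their own number in 0 of 4 cases for Dll4 with Nfatc1-Cre, 0 of 3 with Tie2-Cre, 1 of 3 for Jag1, 0 of 2 for the double knockout and 2 of 4 for MFng, but 2 of 2 for Notch1 and for Jag2, where pairing was not excluded. Apart from the Jag2 count, the block is listed here only. Leaving out 1 library leaves a single wild type for Notch1, Jag2 and the double knockout, which is then assumed to vary like the other group. No alternative was run on the reads, so steps before the deposited values were not varied. For Dll4 with Nfatc1-Cre the 1126 calls became 608 with the replicate block, 2160 at an adjusted p of 0.1, 460 with a 1.5-fold minimum and 1936 after length and GC correction, and 355 to 1752 with 1 library left out (knockout 2 1752, knockout 3 397, knockout 4 355, wild type 1 511, wild type 2 512, wild type 3 391, wild type 4 578). For Dll4 with Tie2-Cre, 3103 became 1056 with a 1.5-fold minimum and 1151 to 2892 with 1 left out (knockout 1 1636, knockout 3 1151, wild type 3 1719). For Notch1, 581 became 153 without trend, 1398 with weights, 1084 with 6 wild types, 1047 after length and GC correction, 269 with DESeq2 and 242 to 727 with 1 left out (knockout 3 374, wild type 2 242). For Jag1, 545 became 2 without trend, 80 with a 1.5-fold minimum, 241 with all 6 groups in the fit, 84 with DESeq2 and 335 to 471 with 1 left out (knockout 2 335, wild type 2 354). For Jag2, 5 became 3 with a pseudocount of 5, 3 with a filter at 5 CPM, 2 without trend, 12 with weights, 58 with the block, 22 with only 2 groups, 8 with DESeq2 and 5 to 9 with 1 left out (9 without knockout 1, knockout 3 or wild type 2). For the double knockout, 136 became 5 without trend, 261 with weights, 711 with the block, 223 at an adjusted p of 0.1, 20 with a 1.5-fold minimum, 331 with only 2 groups and 24 to 488 with 1 left out (knockout 2 79, knockout 3 488, wild type 1 45, wild type 2 24). For MFng, 2079 became 323 with a 1.5-fold minimum and 1548 to 2027 with 1 left out. For the Dll4 drivers, 30 became 5 with a pseudocount of 0.1, 9 with a filter at 5 CPM, 18 with the block, 1 with edgeR and 15 to 47 with 1 left out (Nfatc1-Cre knockouts 1 and 2 15 and 18, wild types 1 to 4 19, 19, 15 and 16; Tie2-Cre knockouts 2 and 3 18 and 19, wild types 1 and 3 47 and 17). For the double against the Jag2 knockout, 6 became 2 without trend, 56 with weights, 100 with the block, 10 at an adjusted p of 0.1, 17 after length and GC correction, 15 with edgeR, 14 with DESeq2 and 5 to 53 with 1 left out (double knockouts 1 and 3 20 and 39, Jag2 knockouts 1 to 3 10, 53 and 13, Jag2 wild type 2 11). Against the Jag1 knockout, 24 became 4 without trend, 43 with weights, 418 with the block, 78 at an adjusted p of 0.1, 10 with a 1.5-fold minimum, 6 with edgeR, 73 with DESeq2 and 7 to 162 with 1 left out (double knockouts 1 to 3 12, 7 and 162, wild types 1 and 2 15 and 9, Jag1 knockout 2 15). Targets with weaker evidence were Jag1 in its knockout without trend (−1.02), Jag2 in its knockout without trend (−0.63) and without wild type 1 (−0.57; −0.69 to −0.57 with 1 left out), and Jag2 in the double knockout without trend (−0.59). Direction turned for Igf2 with quantile normalization (Dll4 Tie2-Cre, 0.0145), Pou3f2 with edgeR in the differences of the double from the Jag2 (−0.81) and Jag1 (−0.10) knockouts, and for medians of lists with 1 library left out, given with the library that turned them and the range over all libraries: fibroblasts (Notch1 without knockout 1, −0.209 to 0.482), ribosomal proteins (Jag2 without knockout 2, −0.00605 to 0.0805), erythroid cells (Jag2 without wild type 1, −0.253 to 0.333) and fatty acid oxidation (double knockout without wild type 2, −0.0811 to 0.0966). Myh7 came to 0 with quantile normalization (MFng). Sex-linked genes in Jag1 knockouts had a median of 0.133 that camera set lower than other genes, and 0.752, set higher, without knockout 1 (−0.223 to 0.752 over all libraries).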

Other observations

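Of the tests in this part, those on called genes and ribosomal protein lists after correction, on the chromosome region and on wild-type means were chosen only after the data were seen.

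Some genes went between near absence (a mean of at most 0.5 CPM) and at least 5 CPM, and all named here were chosen after their values were seen. For Dll4 with Nfatc1-Cre 6 genes did so, all upward: Muc2 (7.23 against 0.306 CPM), Trim66 (6.63 against 0.423) and the urea cycle gene Nags (7.79 against 0.412) besides Sncb, Nxph4 and Gm4673. With Tie2-Cre, Prap1 (18.1 against 0.159) and the pharyngeal gene Pax1 (5.08 against 0.231) were among 4 upward, and Gm8116 (0.5 against 6.83) and Gm14288 (0 against 10.7) went down. The Dll4 Nfatc1-Cre wild types, as listed with the Notch1 libraries, averaged 3.52 CPM for Prap1 and 1.2 for Gm26582, also upward here. Near absence of these genes thus did not hold in those values, while Pax1 (0.442) and Gm9923 (0.135) were low there too. As listed with the Dll4 libraries, Prap1 and Gm26582 failed the filter on low values in the Nfatc1-Cre comparison. Since the values of a library depend on its table, near absence across E9.5 wild types was left open for these genes. In Notch1 knockouts Ctss, Slc25a31 (5.03 against 0.292) and Aqp5 (5.73 against 0.325) went up, and Rbp4 (0.393 against 6.04), Apob, Ttr (0.238 against 5.11) and Apoa1 (0.33 against 5.97) went down. Whether the share of neighbouring tissue differed between these pools was not tested. With MFng, the pyruvate kinase gene Pklr (9.04 against 0.283), Rhag (8.02 against 0.409) and Chac1 (5.6 against 0.421) went up and Alb (0.489 against 10.7, where wild type 4 stood at 27.52 and the others at 4.253 to 6.035) down. Prap1 overlaps Fuom and Pklr overlaps Hcn3 in the annotation, so reads of the neighbour could count for them.

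The inhibitor gene Cdkn1a rose by 0.95 ± 0.226 with Nfatc1-Cre loss of Dll4, by 1.02 ± 0.260 with Tie2-Cre, by 0.45 ± 0.0771 in Jag1 knockouts, by 0.59 ± 0.0851 in double knockouts and by 0.57 ± 0.0901 with MFng (SE). In Notch1 (0.27 ± 0.154) and Jag2 knockouts (−0.09 ± 0.0851) it did not pass. The matrix gene Fbln2 rose in Notch1 (0.87 ± 0.112), Jag1 (0.47 ± 0.0514) and double knockouts (0.41 ± 0.0601) and with MFng (0.43 ± 0.0589). In Jag2 knockouts it did not pass (−0.02, limma adjusted p = 0.999), and its changes in the Dll4 knockouts are not listed here.

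Changes of several comparisons went with transcript length or GC content: Dll4 with Tie2-Cre with length (Spearman 0.205), Notch1 with GC content (−0.23), and the Jag1 and double knockouts, where the correction was followed up. For Jag1 the correlation with length was 0.191, and median exon length was 7420 bases for risen and 3012 for fallen genes. For the double knockout the correlations were −0.279 with length and 0.405 with GC content. After correction 400 of the 545 Jag1 calls (73.4%) and 76 of the 136 double-knockout calls (55.9%) were still called, so such a trend was not the whole source, though it could be part of it. Ribosomal protein genes stayed called, lower in Jag1 knockouts (camera adjusted p = 6.19e-05; adjusted p = 0.490 with an estimated correlation) and higher in double knockouts (3.64e-11; 0.206 with an estimated correlation), with medians that shrank from −0.0798 to −0.0484 and from 0.160 to 0.108.

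Lingo2 and Pou3f2, both on chromosome 4, were near 0 in wild types and higher in knockouts made with cTnT-Cre. Lingo2 lay at 6.76 to 9.97 CPM in Jag2 and 6.12 to 10.6 in double knockouts, against 0.138 to 0.228 in Jag1 knockouts, a single count in each. Within 10 Mb of the genes, 2.26% of genes were called in double knockouts (3 of 133), against 0.96% elsewhere (one-sided Fisher's exact p = 0.140), so a chromosome region that came with an allele or the driver was left open. The adjustment of values between experiments could also have shaped the difference, with an observed to expected ratio of wild-type means of 0.417 for Jag1 against Jag2, but 0.828 and 1.22 for these against the double knockout, and was left open too. The Cre status of the wild types is not in the labels, so an effect of the driver was not tested.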
